A study of Mus musculus with 12 samples.

How the data were processed

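The samples were 12 single-cell RNA libraries of germ cells from C57BL/6 mouse testis, 3 for each of 4 groups: wild type and Zfp541 knockout, collected 260 h or 360 h after retinoic acid. Per the labels' protocols, testes were dissociated with enzymes, single spermatogenic cells were picked by mouth pipette, and barcoded cDNA was made with a modified Smart-seq2 protocol, amplified by PCR, pooled, captured at its 3′ end and sequenced as 150 bp paired ends. The deposited values per library are raw UMI counts (unique molecular identifiers, which mark single cDNA molecules) for each gene and each of 96 cell barcodes. The submitters' processing notes name UMI-tools 1.0.0, STAR 2.5.3a and featureCounts 1.6.4 with the mm10 genome build. Their order and settings, and whether reads were counted by strand, are not given in the sources used here. Antisense genes and genes with near-identical copies are therefore uncertain.

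Each deposited table held 55450 genes and 92 ERCC spike-in sequences, synthetic RNAs added in a known mixture. The spike-ins took 6.35% of all UMIs of the kept cells (3.10% to 11.9% per library) and were left out of library sizes and gene tests. The authors' deposited cell table named 929 of the 1152 barcodes as kept cells, with 5 k-means clusters and 3 classes (pre-meiotic, early pachytene and late pachytene). Its filter and clustering settings are not given in the sources used here, nor is any treatment of doublets, and no doublet caller was run on these hand-picked cells. Only cells in that table were used. Kept cells had 44624 to 565099 gene UMIs (median 116685) and 6223 to 18811 detected genes. A filter of at least 2000 genes and under 10% mitochondrial UMIs removed 0 cells, the highest mitochondrial share being 5.63%. Gene symbols and mm10 coordinates came from the deposited feature table. A symbol shared by several identifiers (108 symbols) was kept apart by identifier.

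Cells are not replicates, so raw counts were summed over the cells of each library and tested across libraries. Genes were kept by filterByExpr, which left 20279. Counts were scaled by TMM, and edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, robust) was fitted to all 12 libraries with 1 coefficient per group, so that the 4 groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.4855. Contrasts were knockout against wild type at 260 h and at 360 h, 360 h against 260 h in each genotype, and the difference between the genotype effects of the 2 times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold threshold. Levels are given as CPM, gene UMIs scaled to counts per 1e6 of the TMM-scaled library, with the mean ± SD over the 3 libraries of a group (n = 3), and log2 fold changes with ± SE. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. No pair of libraries was a duplicate: the chi-square of their counts per degree of freedom was at least 11.0 within groups.

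There were 22 gene lists, fixed before the data were examined: ZFP541 complex, spermatogonia, DNA replication, meiotic entry and early prophase, synaptonemal complex and crossover, pachytene, meiotic division, spermatid, axoneme and cilium, piRNA pathway, sex body and DNA damage signalling, chromatin and histone deacetylase, p53 and apoptosis, immediate early and stress, germ-cell metabolic paralogs, Sertoli, Leydig, peritubular with endothelial, blood and immune, mitochondrial, ribosomal protein, X-linked and Y-linked. Each was tested with camera (limma 3.58.1, preset correlation 0.01, on voom log2 CPM), which compares a list with all other genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Member calls were also adjusted over the list alone. The named genes followed a rule set before the data were examined: Zfp541 always. For the genotype comparisons at each time, they were the 10 called genes with the largest log2 fold change in each direction, with mean CPM of at least 20 over the 6 libraries and no overlap between the groups' libraries, leaving out predicted genes (Gm and Rik symbols), mitochondrial genes and accession-like names. Up to 4 called members per list with the smallest p were added. The other comparisons used the top 5 and up to 2 per list; for the difference between times, non-overlap was required at 360 h and the mean was taken over the 12 libraries. Any other gene is said to have been chosen after its values were seen.

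Shares per library (X-linked and Y-linked UMIs, cell classes, spike-in UMIs, mitochondrial UMIs) were compared with exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.1, so that none could pass 0.05. There were 56 such tests, adjusted together. A class was compared between groups only if no cluster in it had more markers of another class than of its own among its 10 leading genes by fold, with leptotene and zygotene markers counted as pre-meiotic. Late pachytene passed only because its leading genes held no marker of any class. The early pachytene class failed on Cyp11a1, a Leydig cell marker, in cluster 2 and Rad51ap2 and Prss50, markers of earlier prophase, in cluster 3. Its share tests are not reported and it was not fitted. Yet nearly all 260 h cells of the fits without pre-meiotic cells are of this class. The edgeR fit was repeated within a class, on the 6 libraries compared, where at least 2 libraries of each group held at least 10 cells. Pre-meiotic and early pachytene cells at 260 h and late pachytene cells at 360 h met this. Early pachytene cells were left out by the marker check, against the plan. Intervals of shares of genes are exact binomial at 95%. Intervals and floors cover counting error only.

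The fits were tested on simulated counts drawn for the real genes from their mean over the libraries, the real library sizes and the fitted spread, with 200 changed genes. For knockout against wild type at 260 h, edgeR recovered 3 of 100 genes changed 2-fold and 42 of 100 changed 4-fold among 19507 genes tested, and 4.26% of its calls were false. At 360 h it recovered 7 and 50 of 100 among 19463 genes, with 5% false. For 360 h against 260 h it recovered 5 and 40 of 100 in wild type (19459 genes, 4.26% false) and 4 and 37 of 100 in knockout (19456 genes, 4.65% false). For the difference between times it recovered 0 and 10 of 100 (19471 genes, 9.09% false). Most changes of 2-fold at a typical level were thus below what 3 libraries per group could detect. In the same simulated comparisons DESeq2 gave 15% to 25% false calls.

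The alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2's size factors in place of TMM, no filter and a stricter filter on low counts, other cell filters, each cell thinned to 40000 UMIs, the replicate number as a block, a fit on the 6 libraries compared only, and leaving out each library in turn. Scaling by spike-in UMIs, fits without pre-meiotic cells, a thinned fit of late pachytene cells, fits with only 1 library of a group whose libraries differed in cluster make-up, an overlap with the wild-type libraries of 360 h split between the comparisons, and the counts beyond both wild-type groups with the libraries of 360 h split were added after seeing the data. A deposited table of the same counts for a subset of genes named by symbol was not used. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.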

Results

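The data set held single-cell RNA libraries of mouse testis germ cells of 2 genotypes, wild type and Zfp541 knockout, collected at 2 times. Newborn mice had been given an inhibitor of retinoic acid synthesis, which holds spermatogonia undifferentiated, and then an injection of retinoic acid, which lets them enter meiosis together. Testes collected 260 h after the injection were labelled early pachytene and those collected 360 h after it late pachytene. Pachytene is the stage of meiotic prophase at which homologous chromosomes are fully paired. Zfp541 encodes a zinc finger protein of spermatocytes found in a complex with KCTD19 and histone deacetylases. Each group had 3 libraries of 96 barcodes, and 929 cells were kept, 50 to 94 per library. The gene UMIs per library were 3810119, 4873449 and 13094527 in wild type at 260 h, and 10003644, 7363258 and 3601518 in knockout at 260 h. At 360 h they were 13092560, 14799278 and 27202665 in wild type and 8640883, 9527730 and 10689318 in knockout. The median cell of a library had between 7989 and 11241.5 detected genes. The first principal component of the 12 libraries held 49.7% of the variance and the second 13.3%.

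Zfp541 itself (ENSMUSG00000078796.4, mm10 chromosome 7, 16061814 to 16096334, plus strand) was detected in every library of both genotypes. At 260 h it was at 38.1, 84.1 and 129 CPM in the wild-type libraries (161, 473 and 1770 UMIs) and at 123, 99.1 and 75.8 CPM in the libraries labelled knockout (1335, 724 and 368 UMIs). At 360 h the wild-type libraries had 199.8, 178 and 169.6 CPM (2180, 1885 and 3833 UMIs) and the knockout libraries 156, 130.5 and 151 CPM (1239, 1273 and 1661 UMIs). It was not called between the genotypes at either time, with a log2 fold change of 0.24 ± 0.34 at 260 h (adjusted p = 0.846) and −0.32 ± 0.34 at 360 h (adjusted p = 0.532). The assay counts 3′ ends, and the part of the gene that was deleted is not given in the sources used here, so these levels check nothing about the genotype labels. Between the times Zfp541 was higher at 360 h in wild type (log2 fold change 1.12 ± 0.34, adjusted p = 0.0172) and was not called in knockout (0.55 ± 0.34, adjusted p = 0.257).

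The effect of losing Zfp541 in early pachytene was asked by comparing the genotypes at 260 h. In knockout libraries 14 of 51 genes of the sperm tail, 6 of 33 of the pachytene programme and 5 of 18 of germ-cell metabolism were lower. Each of these list calls was lost with an estimated correlation (adjusted p = 0.395, 0.164 and 0.395). Cfap206, a component of the ciliary radial spoke region, was at 15.7 ± 4.88 CPM against 95.8 ± 33.8 in wild type (SD, n = 3 each; log2 fold change −2.60 ± 0.33), and Pgk2, the germ-cell phosphoglycerate kinase, was at 2.17 ± 0.637 against 11.8 ± 4.65 (−2.38 ± 0.40). Genes called higher included the homeobox genes Six5 (54.4 ± 21.8 against 5.68 ± 3.91 CPM) and Pbx3 (36.1 ± 2.38 against 4.03 ± 0.877). Cfap206 lies on chromosome 4 (34688559 to 34730206), Pgk2 on chromosome 17 (40207015 to 40208640), Six5 on chromosome 7 (19094594 to 19098549) and Pbx3 on chromosome 2 (34171457 to 34373142) in mm10. In all, 383 of 20279 genes tested were called, 118 higher and 265 lower, each by at least 2-fold.

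Of 51 axoneme and cilium genes tested, 14 were lower and none higher at 260 h, and 32 were called when adjusted over the list alone (31 lower). The list was lower than other genes (camera adjusted p = 6.97e-18), but not with an estimated correlation (adjusted p = 0.395). Besides Cfap206 its members included Cfap52 (3.33 ± 1.74 against 34.6 ± 14.3 CPM, log2 fold change −3.37), Armc3 (−2.55) and Dnali1, a dynein light intermediate chain (−2.82). The pachytene list had 6 of 33 members lower, and 19 adjusted over the list alone (camera adjusted p = 1.93e-12, adjusted p = 0.164 with an estimated correlation, fry adjusted p = 0.0229). Its members included Insl6 (log2 fold change −2.28), Tcp11 (−2.44) and Piwil1, the PIWI protein of pachytene piRNAs (212 ± 74.4 against 596 ± 302 CPM, −1.49 ± 0.36). Piwil1 was also the 1 member called of 26 piRNA pathway genes, and 1 was called adjusted over the list alone (camera adjusted p = 1.05e-04, adjusted p = 0.507 with an estimated correlation). Of 18 germ-cell metabolic paralogs 5 were lower, and 10 adjusted over the list alone (camera adjusted p = 5.25e-06, adjusted p = 0.395 with an estimated correlation). With Pgk2 they included Eno4, a sperm enolase (−2.06), the glucose transporter gene Slc2a3 (106 ± 14.7 against 383 ± 174 CPM, −1.85) and Pdha2, the germ-cell pyruvate dehydrogenase subunit (118 ± 39.7 against 287 ± 45.3 CPM, −1.28).

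Of 31 meiotic entry and early prophase genes, 3 were called at 260 h, and 3 adjusted over the list alone. Gm4969 (Meiosin, a partner of STRA8 in meiotic entry) was at 26.6 ± 15.4 CPM in knockout against 0.915 ± 0.456 (log2 fold change 4.73 ± 0.75, adjusted p = 0.00432). It faces Six5 and, with strand unknown, is uncertain. Ugt8a was higher (2.23 ± 0.53, adjusted p = 0.0410). Spo11, which makes the DNA breaks of recombination, was lower, at 26.7 ± 5.75 against 78.8 ± 38.2 CPM (−1.56 ± 0.34, adjusted p = 0.0274). That list was not called (camera adjusted p = 0.0738), and its median of −0.03 and mean of 0.37 differed in sign. Acr and Actl7b were the 2 of 24 spermatid genes called, both lower, and 8 were called adjusted over the list alone. Fbxo43, an inhibitor of the anaphase-promoting complex, was the 1 of 35 meiotic division genes called (10.9 ± 0.234 against 30.2 ± 5.65 CPM, −1.46 ± 0.26). Hsd3b1, a Leydig cell steroid enzyme, was lower (−5.61 ± 1.24, adjusted p = 0.0295). It stood at 22.5, 10.3 and 0.364 CPM in the wild-type libraries and at 0.206 ± 0.0693 in knockout. The complement gene C1qa, a macrophage marker, had 12.1, 16.0 and 0.0728 CPM in the same wild-type libraries. Wild-type libraries 1 and 2 thus held somatic transcripts at levels that wild-type library 3 and the knockout libraries did not, and the axoneme, pachytene and metabolic lists were compared across the same libraries.

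The remaining genes with the largest fold changes at 260 h were of mixed kinds. Higher in knockout were Rasgrp2, an activator of Ras-family GTPases (96.1 ± 25.5 against 17.8 ± 14.5 CPM), Asns, the asparagine synthetase gene (56.7 ± 15.2 against 11.7 ± 10.97), Rex1bd, Tm7sf3, Kank3, Tmem160, Prss41 and Macrod2, with log2 fold changes from 2.20 to 2.45. Lower were Prok2, encoding a secreted prokineticin (4.48 ± 1.55 against 76.6 ± 67.1 CPM, −4.11), Zfp820 (10.3 ± 1.64 against 169 ± 15.1, −4.04), March10 (−3.26), Pou2f2 (−3.14), Crisp2 (26.7 ± 17.1 against 210 ± 65.6, −2.97), Mroh2b (−2.91), Tmbim7 (−2.78), Dnhd1 (−2.70) and Prps1l1 (−2.69). With camera 3 further lists were called higher with no member called: p53 and apoptosis (adjusted p = 0.0144, median log2 fold change 0.31), ribosomal protein (5.08e-04, median 0.12) and X-linked (0.00554, median 0.09). Each was lost with an estimated correlation (adjusted p = 0.507, 0.795 and 0.795). The p53 call was also lost without wild-type library 2 (0.0641) or knockout library 3 (0.0501). The X-linked call was lost without wild-type library 2 (0.146), wild-type library 3 (0.738) or knockout library 3 (0.0655), and turned direction without pre-meiotic cells (0.614). The ribosomal call was lost without wild-type library 2 (0.240), knockout library 1 (0.275) or knockout library 2 (0.708), and turned direction without wild-type library 3 (0.838). Lists not called at 260 h were DNA replication (camera adjusted p = 0.309), spermatogonia (0.188), synaptonemal complex and crossover (0.272), meiotic division (0.156), spermatid (0.156), sex body and DNA damage signalling (0.537), chromatin and histone deacetylase (0.857), immediate early and stress (0.391), ZFP541 complex (0.857), Sertoli (0.271), Leydig (0.309), peritubular with endothelial, blood and immune (0.391), mitochondrial (0.219) and Y-linked (0.309). The median and mean differed in sign for sex body (−0.03 and 0.08), spermatogonia (−0.05 and 0.19) and Y-linked genes (−0.04 and 0.17). Camera's direction was against both for spermatid genes (lower, 0.0064 and 0.23), chromatin (higher, −0.03 and −0.05) and peritubular genes (higher, −0.35 and −0.61).

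The count at 260 h rested on few libraries: it was 577 without wild-type library 1, 115 without wild-type library 2, 158 without knockout library 1, 184 without knockout library 3, and 122 with wild-type library 3 as the only wild-type library. Scaled by spike-in UMIs, 31 genes were higher and 215 lower, so that 12.6% of the calls were higher against 30.8% with TMM. That scaling moved the median log2 fold change of all genes by −0.28, more than the medians of the ribosomal protein and X-linked lists. The list medians were not computed with that scaling. It rested on wild-type library 3: the knockout to wild-type ratio of gene UMIs per spike-in UMI was 0.786, and 1.09 without that library. With limma-voom 92 genes were higher and 84 lower (52.3% higher), with only the 6 libraries compared 81 and 100 (44.8%), without pre-meiotic cells 248 and 352 (41.3%), with thinned cells 139 and 199 (41.1%), with all barcodes of at least 500 genes 46 and 184, and leaving out a library gave 17.9% to 36.0% higher. Within pre-meiotic cells alone 4 genes were called with edgeR (12223 tested), and 1181 had an unadjusted p under 0.05. Chosen after their values were seen, these were Akap7 (log2 fold change 3.05), Pcsk1n (3.62) and Gm26822, all higher, and n-R5s196, which was lower. In those cells the axoneme (median log2 fold change −0.98, camera adjusted p = 4.26e-09), pachytene (−1.07, 3.4e-13), metabolic (−1.14, 1.09e-08) and piRNA (−0.52, 1.21e-06) lists were lower with no member called, against medians of −1.19, −0.78, −0.68 and −0.38 in all cells. The call of each was lost with an estimated correlation (adjusted p = 0.364). The peritubular, endothelial, blood and immune list was higher there (median 0.22, camera adjusted p = 0.0210, adjusted p = 0.873 with an estimated correlation).

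The same question in late pachytene was asked at 360 h, where the genotypes differed in many more genes. In knockout 33 of 51 sperm tail, 12 of 24 spermatid and 18 of 33 pachytene genes were lower, while 15 of 31 genes of meiotic entry and 11 of 21 of recombination and synapsis were higher. Each of these list calls was lost with an estimated correlation (adjusted p = 0.294). Ccna1, the cyclin A1 gene needed for the meiotic divisions, was at 4.79 ± 0.918 CPM in knockout against 71.9 ± 13.3 in wild type (SD, n = 3 each; log2 fold change −3.90 ± 0.45), and Prdm9, the histone methyltransferase that marks recombination hotspots, was at 65.3 ± 17.4 against 4.29 ± 0.694 (3.92 ± 0.52). Ccna1 lies on chromosome 3 (55045469 to 55055501) and Prdm9 on chromosome 17 (15543079 to 15564354). In all 4554 of 20279 genes were called, 1811 higher and 2743 lower, of which 1706 and 2521 differed by at least 2-fold.

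Of 31 meiotic entry and early prophase genes, 15 were higher at 360 h and none lower, and 15 adjusted over the list alone (camera adjusted p = 3.29e-06, 0.294 with an estimated correlation). Zcwpw1, a reader of the PRDM9 mark, was at 399 ± 63.1 CPM against 30.3 ± 6.83 (log2 fold change 3.72 ± 0.48). The uncertain Gm4969 was at 44.0 ± 13.0 against 0.985 ± 0.980 (5.37 ± 0.74) and Ugt8a at 29.96 ± 5.10 against 1.97 ± 1.41 (3.90 ± 0.56). Of 21 synaptonemal complex and crossover genes, 11 were higher and none lower, and 13 adjusted over the list alone (camera adjusted p = 6.3e-05, 0.294 with an estimated correlation). They included the crossover helicase gene Hfm1 (449 ± 53.1 against 82.3 ± 0.531 CPM, 2.45 ± 0.27), Mcmdc2, which acts in recombination (116 ± 20.97 against 12.9 ± 3.74, 3.17 ± 0.33), Msh5 (79.8 against 15.1) and Tex12, of the central element (373 against 99.7, 1.90). Spermatogonia genes had 6 of 29 higher and 1 lower, and 7 adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.624 with an estimated correlation): Dazl (378 ± 138 against 142 ± 29.4 CPM), Uchl1 (1.91) and Dnmt3b (2.47) were higher and Dmrtb1 (−2.36) was lower. DNA replication genes had 7 of 25 higher and 2 lower, and 9 adjusted over the list alone (camera adjusted p = 0.0303, adjusted p = 0.624 with an estimated correlation), among them Mcm5 (68.8 against 19.0 CPM, 1.86), Mcm3 (1.57), Prim1 (1.72) and Mcm6 (1.18). The spermatogonia call was lost without knockout library 2 (0.0570) or 3 (0.0526) and among late pachytene cells alone (4 of 26 higher and 2 lower, 0.104), and the DNA replication call without wild-type library 3 (0.0767) or knockout library 2 (0.0679).

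**Figure D1:**
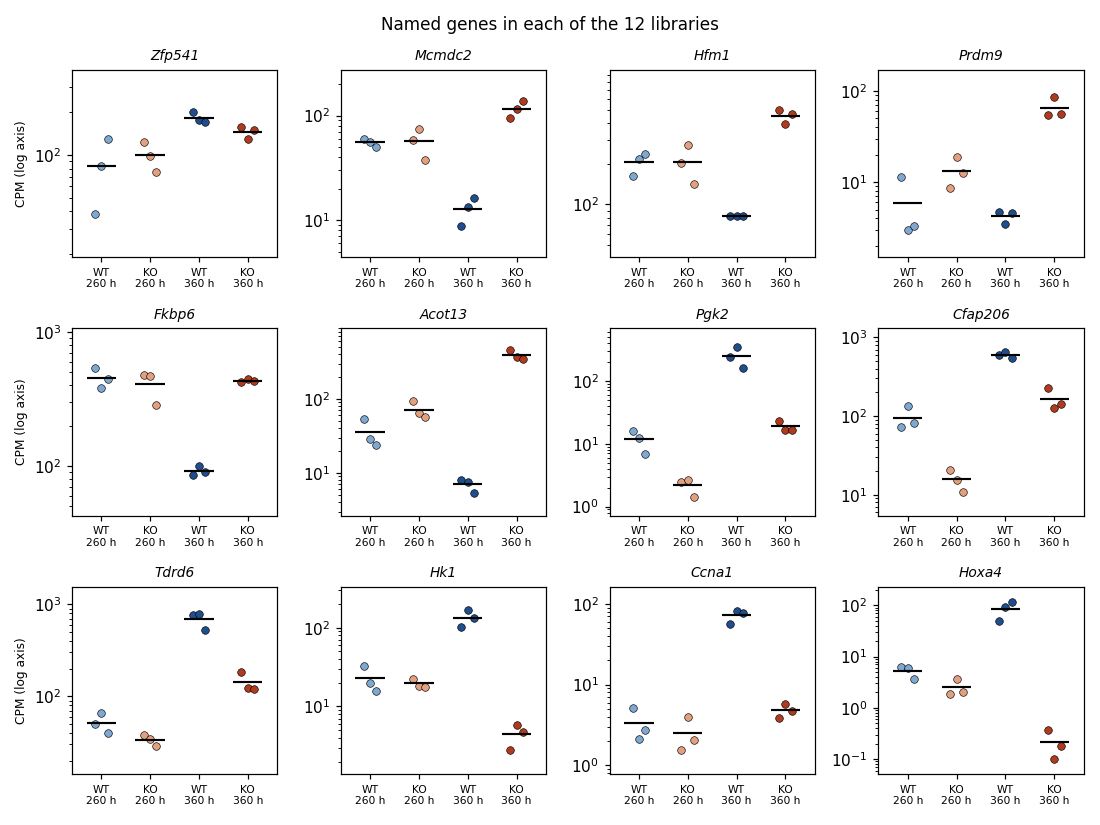
Expression of 12 named genes in CPM (log axis) in the 4 groups; each point is a library and each bar the mean of 3 libraries. Mcmdc2, Hfm1, Prdm9, Fkbp6 and Acot13 were higher and Pgk2, Cfap206, Tdrd6, Hk1, Ccna1 and Hoxa4 lower in knockout at 360 h, while Zfp541 was not called at either time.

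Lower at 360 h were 33 of 51 axoneme and cilium genes, with none higher, and 38 adjusted over the list alone (camera adjusted p = 2.88e-14, adjusted p = 0.294 with an estimated correlation). They included the dynein heavy chain gene Dnah10 (9.53 against 87.9 CPM, log2 fold change −3.21), Ccdc40 (56.9 ± 4.68 against 293 ± 80.3, −2.36) and Spag17 (289 ± 69.8 against 869 ± 151, −1.59). Tekt3, a tektin of flagellar microtubules, was at 1.04 ± 0.279 against 245 ± 86.0 CPM (−7.88 ± 1.09). The pachytene list had 18 of 33 members lower and 1 higher, and 21 adjusted over the list alone (camera adjusted p = 3.48e-07, adjusted p = 0.294 with an estimated correlation). Beside Ccna1 and Pgk2 (18.8 ± 3.95 against 247 ± 92.3 CPM, −3.72 ± 0.38) these included Ovol2, a zinc finger transcription factor gene (1.21 ± 0.921 against 103 ± 33.3, −6.44 ± 0.65), and Tbpl1, a TBP-related factor gene (125 ± 9.24 against 500 ± 123, −2.00). Of 24 spermatid genes 12 were lower, and 17 adjusted over the list alone (camera adjusted p = 1.65e-05, adjusted p = 0.294 with an estimated correlation), with the acrosomal gene Acrbp at 83.0 ± 5.29 against 650 ± 219 CPM (−2.97), Tssk1 (−4.04), Zpbp (−1.94) and Catsper2, of the sperm calcium channel (−1.48). Of 18 metabolic paralogs 9 were lower, and 12 adjusted over the list alone (11 lower; camera adjusted p = 3.58e-04, adjusted p = 0.375 with an estimated correlation). Hk1, a hexokinase gene, was at 4.47 ± 1.56 against 134 ± 31.5 CPM (−4.89 ± 0.39), and Gk2, a glycerol kinase gene, at 159 against 779 (−2.29).

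Some other lists had calls both ways at 360 h. The piRNA pathway had 6 of 26 higher and 4 lower, and 12 adjusted over the list alone (camera adjusted p = 0.605). Fkbp6 was at 435 ± 10.5 against 91.3 ± 7.13 CPM (log2 fold change 2.25) and Btbd18, a regulator of pachytene piRNA transcription, at 33.4 against 3.16 (3.41), while Tdrd6, of the chromatoid body, was at 143 ± 34.7 against 692 ± 146 (−2.27) and Tdrd7 at 53.7 against 196 (−1.87). Meiotic division had 2 of 35 higher and 5 lower, and 7 adjusted over the list alone (camera adjusted p = 0.208): the shugoshin gene Sgo1, which protects centromeric cohesion, was higher (74.5 ± 5.22 against 6.46 ± 2.49 CPM, 3.54), and the meiotic kinase gene Aurkc (4.88 ± 2.54 against 124 ± 52.6, −4.66), Fbxo43 (−1.03) and Ttk (−0.92) were lower. Chromatin and histone deacetylase genes had 4 of 33 higher and 4 lower, and 8 adjusted over the list alone (camera adjusted p = 0.797): the histone methyltransferase gene Ehmt1 (57.2 ± 9.21 against 4.26 ± 1.48 CPM, 3.76), the demethylase gene Kdm5a (1.35) and Rnf2 (1.11) were higher and Brd3 (−0.94) lower. The p53 and apoptosis list had 4 of 23 higher and 2 lower, and 6 adjusted over the list alone (camera adjusted p = 0.163). Apaf1, the apoptosome scaffold gene, was at 25.5 ± 1.48 against 1.84 ± 0.688 CPM (3.804), with Trp53inp1 (1.86) and Bax (1.64) also higher and Zmat3 lower (−2.27). Sex body and DNA damage signalling had 4 of 24 higher and 3 lower, and 11 adjusted over the list alone (camera adjusted p = 0.551): Atrip (1.80) and Rad9b (0.78) were higher and Rnf168, a ubiquitin ligase gene of damage signalling (34.4 ± 5.92 against 142 ± 8.32 CPM, −2.05), and Rad9a (−2.63) lower. Of 27 immediate early and stress genes 4 were lower, and 3 adjusted over the list alone (camera adjusted p = 0.442), with Xbp1 at −2.00, Dnajb1 at −1.35 and Jun at −1.28. In the ZFP541 complex list 2 of 7 were higher, and 2 adjusted over the list alone (camera adjusted p = 0.605): Trerf1 (1.98) and Elmsan1 (2.48). The medians of the ZFP541 complex (−0.12), chromatin (−0.08) and piRNA (−0.05) lists were below 0 and their means (0.48, 0.14 and 0.13) above it. The immediate early list had a median of 0.70 and a mean of 0.41, above 0 although its called members were lower.

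The genes with the largest fold changes upward at 360 h included Bend6 (50.2 ± 0.923 against 0.633 ± 0.345 CPM, log2 fold change 6.22), Dhrs3, a retinaldehyde reductase gene (126 ± 39.0 against 2.00 ± 1.14, 6.00), Acot13, an acyl-CoA thioesterase gene (387 ± 55.4 against 6.97 ± 1.46, 5.80), Clca3b (6.62), Dip2c (5.27), the fatty acid desaturase gene Fads1 (125 against 3.33, 5.23), Arhgap21 (5.16) and Mpv17l2 (5.08). Six5 (170.1 ± 8.33 against 3.26 ± 1.84 CPM, 5.68) and Tmem160 (114 ± 48.9 against 1.14 ± 0.850, 6.53) were called higher at both times. Downward, Hoxa4 was at 0.221 ± 0.142 against 85.9 ± 34.2 CPM (−8.58 ± 0.60), with 6 UMIs over the 3 knockout libraries, and Ccdc178 (−8.55), Hyal6 (−7.26), Csl (−7.18), Slamf7 (−7.17), Susd5 (−7.04), Slco6c1 (4.16 against 525 CPM, −6.96) and Gtsf2 (−6.84) followed. Frs3os (−6.88) is named as an antisense gene and is uncertain.

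Lists of other kinds were called higher by camera at 360 h as well. Over all genes 1811 of 20279 were called higher, a larger share than in the ribosomal protein, Sertoli and X-linked lists. Mitochondrial genes had 7 of 24 higher, and 7 adjusted over the list alone (camera adjusted p = 1.65e-05, adjusted p = 0.294 with an estimated correlation). The calls included the short transfer RNA genes mt-Tm, mt-Tv, mt-Tl2 and mt-Tq. Mitochondrial UMIs were 2.23% ± 0.263 of the total in knockout and 1.33% ± 0.258 in wild type (exact permutation p = 0.1, adjusted p = 0.243). Ribosomal protein genes had 5 of 84 higher, among them Rpl22 (418 against 194 CPM), and 0 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.746 with an estimated correlation). Sertoli genes had 1 of 21 higher, Ctsl (log2 fold change 1.65), and 1 adjusted over the list alone (camera adjusted p = 5.59e-04, adjusted p = 0.584 with an estimated correlation). Leydig genes had 1 of 10 higher, Dlk1 (camera adjusted p = 0.0524), and 0 adjusted over the list alone. X-linked genes had 29 of 592 higher and 3 lower, Fthl17-ps3 (−3.28), H2afb3 (−4.55) and Cylc1 (−5.07), which were chosen after their values were seen. Adjusted over the list alone 2 were called, both lower (Fthl17-ps3 and H2afb3), while the list as a whole was higher (camera adjusted p = 3.29e-06, adjusted p = 0.645 with an estimated correlation). None of 25 peritubular, endothelial, blood and immune genes (camera adjusted p = 0.551, median 0.27 and mean −0.06) or of 11 Y-linked genes (0.208) was called. Among late pachytene cells alone the calls of the mitochondrial (12 of 22 higher, camera adjusted p = 2.44e-05), ribosomal protein (19 of 84, 2.02e-06), Sertoli (4 of 20, 0.00268) and X-linked (20 of 334 and 3 lower, 9.13e-05) lists were made too, and lost with an estimated correlation (adjusted p = 0.396, 0.607, 0.607 and 0.607).

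The count at 360 h was 2816 without knockout library 2 and 2600 without knockout library 3, and 996 with knockout library 1 as the only knockout library. Scaled by spike-in UMIs, 637 genes were higher and 3091 lower, so that 17.1% of the calls were higher against 39.8% with TMM. That scaling moved the median of all genes by −0.50, more than the medians of the ribosomal protein (0.23) and DNA replication (0.34) lists. The list medians were not computed with that scaling. Among cells of the late pachytene class alone, which were in cluster 4 in knockout and in cluster 5 in wild type at 360 h, 5858 of 16803 genes were called (2598 higher, 3260 lower), and 4297 of the calls in all cells were found there in the same direction. In those cells axoneme genes had 35 of 51 lower and 1 higher (camera adjusted p = 2.47e-10, adjusted p = 0.449 with an estimated correlation). Meiotic entry genes had 15 of 29 higher (3.79e-06, 0.219 with an estimated correlation) and synaptonemal complex and crossover genes 12 of 21 (7.82e-05, 0.219 with an estimated correlation).

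The change between the collection times was asked in wild type. By 360 h 47 of 51 sperm tail, 19 of 33 pachytene and 15 of 24 spermatid genes had risen. By then 20 of 29 spermatogonia, 12 of 21 synapsis and crossover and 300 of 592 X-linked genes had fallen. Each of these list calls was lost with an estimated correlation. Hydin, of the axonemal central pair, rose from 44.1 ± 6.20 to 284 ± 54.0 CPM (SD, n = 3 each; log2 fold change 2.69 ± 0.26), and Sycp1, of the synaptonemal complex, fell from 1587 ± 271 to 363 ± 72.3 (−2.13 ± 0.26). Hydin lies on chromosome 8 (110266977 to 110610253) and Sycp1 on chromosome 3 (102818499 to 102936100). In all 8082 genes were called, 4244 higher and 3838 lower, 3862 and 3540 by at least 2-fold. Without pre-meiotic cells (27.1% of cells, then 1.86%) 3569 higher and 2719 lower calls were kept. Axoneme and cilium genes had 47 of 51 higher (camera adjusted p = 1.72e-22, 0.333 with an estimated correlation), with Drc7 at log2 fold change 3.55. Pachytene genes had 19 of 33 higher and 1 lower (1.46e-07, 0.333 with an estimated correlation), with Pgk2 at 4.41 and Fhl4 at 3.56. Spermatid genes had 15 of 24 higher (1.1e-04, 0.375 with an estimated correlation), with Zpbp2 at 3.96 and Acrbp at 3.40. Metabolic paralogs had 10 of 18 higher and 2 lower (3.25e-04, 0.375 with an estimated correlation), with the fructose transporter gene Slc2a5 at 3.75. Adjusted over the list alone, 48, 21, 18 and 13 members of these 4 lists were called.

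Lower in wild type at 360 h were 20 of 29 spermatogonia genes, with 1 higher (camera adjusted p = 1.46e-07, adjusted p = 0.375 with an estimated correlation), among them Dazl (log2 fold change −3.03) and Tcl1 (−5.36). Synaptonemal complex and crossover genes had 12 of 21 lower and 4 higher (0.00937, 0.375 with an estimated correlation), with Mcmdc2 at −2.10. Meiotic entry genes had 12 of 31 lower and 2 higher (0.0168, 0.426 with an estimated correlation), with Hormad2 at −2.64 and Meiob at −2.48. X-linked genes had 300 of 592 lower and 6 higher (8.78e-13, 0.410 with an estimated correlation), with Hmgn5 falling from 57.3 to 3.07 CPM, and Y-linked genes 10 of 11 lower (0.00288, 0.375 with an estimated correlation). Chromatin genes had 14 of 33 lower and 2 higher (0.0135, 0.510 with an estimated correlation), with Hdac2 at −1.73, and p53 and apoptosis genes 9 of 23 lower and 2 higher (0.00288, 0.375 with an estimated correlation), with Apaf1 at −3.34 and Bax at −2.89. Immediate early and stress genes had 15 of 27 lower and 2 higher (6.17e-04, 0.375 with an estimated correlation). Leydig genes had 6 of 10 lower (0.0266, 0.375 with an estimated correlation) and Sertoli genes 4 of 21 (0.0135, 0.555 with an estimated correlation), with Hsd3b1 at −5.69. The macrophage gene C1qa was called lower too (−5.21 ± 1.42), but was at 1.57 on the log2 scale with wild-type library 3 as the only library at 260 h. The Leydig and Sertoli calls were lost without wild-type library 3 of 360 h (0.0641 and 0.0845), and the chromatin call without wild-type library 3 of 260 h (0.0901). Adjusted over the list alone, the counts called were 24 spermatogonia, 16 synaptonemal complex, 18 meiotic entry, 329 X-linked, 11 Y-linked, 16 chromatin, 12 p53, 18 immediate early, 7 Leydig and 2 Sertoli.

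Lists not called with time in wild type were DNA replication (camera adjusted p = 0.0574), meiotic division (0.489), piRNA pathway (0.579), sex body and DNA damage signalling (0.157), ZFP541 complex (0.579), peritubular with endothelial, blood and immune (0.513), mitochondrial (0.0530) and ribosomal protein (0.136). Kctd19, of the ZFP541 complex, rose from 145 to 343 CPM (log2 fold change 1.24 ± 0.27, adjusted p = 0.00214), and Tdrd6 rose by 3.74 and Mcm3 fell with a log2 fold change of −2.94. By size alone the genes that rose most were Gpr62 (6.81), Itprip (6.77), Ggn (3.003 to 258 ± 28.8 CPM, 6.43), Pou5f2 (6.25) and Mospd4 (6.18), and those that fell most were Mdk (−5.67), Sohlh2, a spermatogonial transcription factor gene (123 ± 71.6 to 4.53 ± 4.27 CPM, −4.80), Rad51ap2 (−4.79), Cd82 (−4.73) and Arhgef25 (−4.72). The count was 4989 with wild-type library 3 as the only wild-type library at 260 h. Scaled by spike-in UMIs, 4432 genes were higher and 1683 lower, 72.5% higher against 52.5% with TMM, with the median of all genes moved by 0.43.

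Whether the genes that changed with time in wild type were those that differed in knockout at 360 h was asked by overlap. Of the genes that fell with time in wild type, 1237 were higher in knockout at 360 h, where independent lists would share 343, and of those that rose, 2060 were lower in knockout, against 574. The first set held Ehmt1, Mcmdc2, Hfm1, Zcwpw1, Fkbp6 and Dazl, and the second Pgk2, Ccna1, Hk1, Tdrd6, Acrbp, Ccdc40 and Spag17. Prdm9 was not in the first set, as it was not called with time (log2 fold change −0.41, adjusted p = 0.529). In the same direction 29 genes were higher in both, against 379, and 12 lower, against 519. Across genes, which are not independent replicates, r and rho of the 2 log2 fold changes were −0.73. The comparisons share the wild-type libraries of 360 h with opposite sign, and 20 simulations with no effect gave r = −0.48 and, with hardly a call, no test of overlap. The covariance was −2.50 (−0.24 simulated, difference −2.26). The wild-type libraries of 360 h were split each of 6 ways, so that none was shared. Of them 1 or 2 gave the change with time and the others the knockout effect. A lone library was then taken to vary like the other groups. The first count was 345 to 654, where independent lists would share 63.5 to 158, and the second 843 to 1482, against 191 to 381. Then r was −0.61 to −0.55, against −0.01 simulated, and the covariance −2.50 to −2.01, against −0.0091. The first count was 730 without wild-type library 2 of 360 h, 712 without knockout library 2 of 360 h and 751 without knockout library 3 of 360 h, and the count of 2060 was 1231 without knockout library 3.

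**Figure D2:**
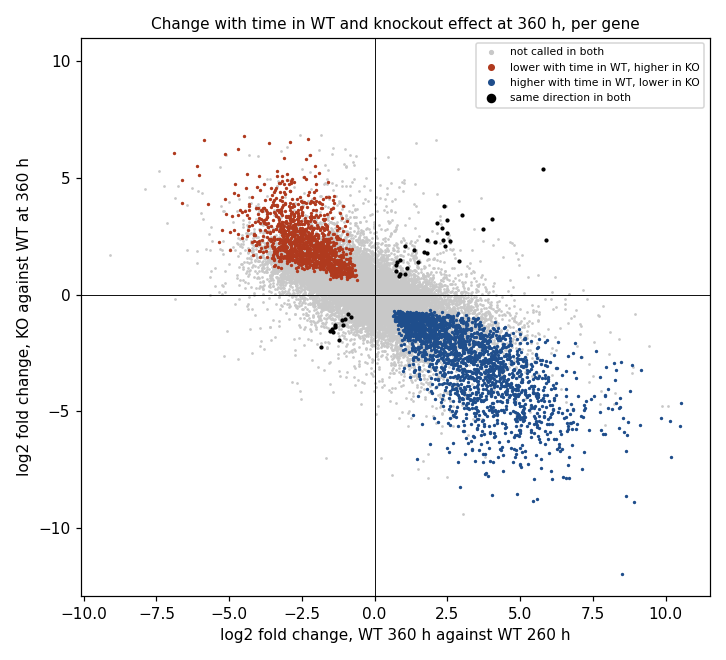
Each point is a gene, with its log2 fold change at 360 h against 260 h in wild type on the x axis and knockout against wild type at 360 h on the y axis. Red marks the 1237 genes lower with time and higher in knockout, blue the 2060 genes higher with time and lower in knockout, black genes called in the same direction and grey the others.

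The 260 h and 360 h genotype comparisons share no libraries. There 70 genes were higher in knockout at both times, against 10.5 for independent lists, and 197 were lower at both, against 35.8. Opposite directions held 2 and 4 genes, against 23.7 and 16.0. Across genes r was 0.28, against 0.0035 simulated, with a covariance difference of 0.51. Without wild-type library 2 of 260 h the counts of 70 and 197 were 15 and 74, without knockout library 1 of 260 h 19 and 85, and without knockout library 3 of 260 h 33 and 96. The count of 70 was also 33 without knockout library 2 of 260 h, 45 without wild-type library 3 of 260 h and 34 without knockout library 3 of 360 h, and that of 197 was 125 without knockout library 2 and 130 without knockout library 3 of 360 h. Set beside the change with time in knockout, which shares the knockout libraries of 360 h, 195 genes were lower with time and higher in knockout, against 185, and 733 the reverse, against 364 (r = −0.07, 0.50 simulated, covariance difference −0.44). Over the left-out libraries these counts were 50 to 192 and 345 to 854. They were 50 and 345 without knockout library 3 of 360 h and 65 and 389 without knockout library 2 of 360 h, and the first was 73 and 86 without knockout library 1 or 2 of 260 h and 118 without wild-type library 2 of 360 h. The correlation r turned positive without knockout library 1 (0.035), 2 (0.062) or 3 (0.037) of 360 h and without wild-type library 2 of 360 h (0.0012).

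The change with time in knockout was asked likewise. In knockout 41 of 51 sperm tail and 17 of 33 pachytene genes rose, and 12 of 29 spermatogonia and 59 of 592 X-linked genes fell. Each of these list calls was lost with an estimated correlation, and the X-linked call also without pre-meiotic cells (adjusted p = 0.220). The share of X-linked genes called lower was near that of all genes tested, 2066 of 20279. Hydin rose from 17.1 to 130 CPM (log2 fold change 2.93 ± 0.27), Tcp11 by 4.59 ± 0.45 and Spo11 from 26.7 to 117 CPM (2.13 ± 0.35). In all 4759 genes were called, 2693 higher and 2066 lower, 2399 and 1937 by at least 2-fold. Without pre-meiotic cells 2204 higher and 1337 lower calls were kept. Axoneme and cilium genes had 41 of 51 higher (camera adjusted p = 2.04e-24, 0.306 with an estimated correlation), with Cfap206 at 3.39. Pachytene genes had 17 of 33 higher (1.69e-07, 0.306 with an estimated correlation), metabolic paralogs 10 of 18 higher and 2 lower (0.00100, 0.436 with an estimated correlation), with Slc2a5 at 3.11, and the piRNA pathway 5 of 26 higher and 1 lower (0.0471, 0.686 with an estimated correlation), with Tdrd6 at 2.09. Spermatogonia genes had 12 of 29 lower (1.69e-07, 0.386 with an estimated correlation), with Dazl at −1.70 and Ccnd1 at −4.29, and X-linked genes 59 of 592 lower and 5 higher (2.05e-09, 0.624 with an estimated correlation). Also lower were Y-linked genes (3 of 11; 0.00247, 0.436 with an estimated correlation), p53 and apoptosis (9 of 23; 3.86e-04, 0.312 with an estimated correlation), immediate early and stress (8 of 27, 1 higher; 4.38e-05, 0.393 with an estimated correlation) and chromatin (8 of 33, 1 higher; 0.00504, 0.624 with an estimated correlation). Adjusted over the list alone, the counts called were 43, 22, 13, 6, 14, 13, 5, 9, 12 and 12 in the order given. The piRNA call was lost without pre-meiotic cells (adjusted p = 0.660) and also without knockout library 3 of 260 h (0.126) or knockout library 2 of 360 h (0.0550), and the chromatin call without knockout library 2 of 260 h (0.0654).

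Lists not called with time in knockout were spermatid (7 of 24 higher and 1 lower, camera adjusted p = 0.0887), synaptonemal complex and crossover (8 of 21 higher and 2 lower, 0.0729), meiotic entry (7 of 31 higher and 4 lower, 0.394, median 0.29 and mean −0.04), sex body (0.227), mitochondrial (0.227), DNA replication (0.277), meiotic division (0.364), ribosomal protein (0.510), peritubular (0.510), Sertoli (0.574), ZFP541 complex (0.904) and Leydig (0.904). The genes with the largest falls were Mir6236 (log2 fold change −6.52), Hist1h1e (−5.58), Rad51ap2 (−5.02), Cdkn1c (62.9 to 1.97 CPM, −4.96) and Tsen34 (−4.59). Those that rose most, Tcp10c, Tcp10a and Tcp10b (7.13, 6.48 and 5.88) with Kbtbd8os and Gldnos (6.55 and 6.35), are close paralogs or antisense genes and are uncertain. The count was 2764 without knockout library 1 of 360 h, 3090 without knockout library 1 of 260 h, and 2636 with knockout library 1 as the only knockout library of 360 h. Scaled by spike-in UMIs it was 2567 (2084 higher, 483 lower), 81.2% higher against 56.6%, with the median of all genes moved by 0.21.

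Whether the knockout effect differed between the times was tested directly. The effect was more positive at 360 h for 8 of 21 synapsis and crossover genes and more negative for 2 of 24 spermatid genes. Both list calls were lost with an estimated correlation (adjusted p = 0.354 and 0.817). The 2 spermatid genes, Tnp2 and Tssk3, rest on groups with almost no UMIs. The difference of log2 fold changes was 4.79 ± 0.47 for Acot13 and 3.12 for Mcmdc2, and −7.55 ± 0.73 for Hoxa4 and −3.52 for Ccna1. In all 1030 genes were called, 467 more positive and 563 more negative at 360 h. Synaptonemal complex and crossover genes had 8 of 21 more positive, and 11 adjusted over the list alone (camera adjusted p = 6.81e-07, adjusted p = 0.354 with an estimated correlation). Meiotic entry genes had 3 of 31 more positive, and 9 adjusted over the list alone (6.46e-05, 0.581 with an estimated correlation). Spermatid genes had 2 of 24 more negative, and 2 adjusted over the list alone (0.00390, 0.817 with an estimated correlation). The piRNA pathway had 2 each way (0.0120, 0.862 with an estimated correlation) and Leydig genes 1 more positive (0.0199, 0.690 with an estimated correlation), with 10 and 3 called adjusted over the list alone. Sertoli (0.0199, 0.981 with an estimated correlation), mitochondrial (0.00267, 0.690) and X-linked genes (0.00390, 0.981) had no member called over all genes or adjusted over the list alone. Leaving out a library ended the Leydig call (0.0606 without knockout library 1 of 260 h, 0.0553 without wild-type library 3 of 360 h) and the spermatid call (0.0545 without wild-type library 3 of 360 h). It ended the X-linked call without wild-type library 1 of 260 h (0.371) and knockout libraries 2 (0.147) and 3 (0.269) of 360 h. The Sertoli call was lost without pre-meiotic cells (0.0830), and without wild-type library 1 (0.0846) or knockout library 2 (0.0659) of 260 h, or wild-type library 3 (0.237) or knockout library 3 (0.153) of 360 h. By size Dhrs3 (6.75), Anp32e (4.63), Sbk1 (4.54) and Arhgap21 (4.32) were more positive, and Ovol2 (−6.74), Zbtb42 (−6.52), Pou5f2 (−6.16) and Arc (−5.81) more negative. The pachytene list was not called (camera adjusted p = 0.608), and its median of 0.06 and mean of −0.40 differed in sign. So did those of the chromatin (−0.01 and 0.18), p53 (0.05 and −0.12) and sex body (0.30 and −0.06) lists. The peritubular list had a median of 0.83 and a mean of 0.55 with camera's direction negative (adjusted p = 0.947).

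The count of 1030 was 638 without wild-type library 2 of 260 h, 594 without knockout library 2 of 260 h, 615 without wild-type library 2 of 360 h, 501 without knockout library 2 of 360 h and 482 without knockout library 3 of 360 h, 636 with wild-type library 3 as the only wild-type library of 260 h, and 191 with knockout library 1 as the only knockout library of 360 h. Scaled by spike-in UMIs it was 408 (75 more positive, 333 more negative), 18.4% more positive against 45.3%, with the median of all genes moved by −0.23.

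The silencing of the X chromosome in pachytene was asked from the share of UMIs of X-linked genes. At 360 h it was 0.425% ± 0.200 in knockout and 0.194% ± 0.0322 in wild type (SD, n = 3 each; exact two-sided permutation p = 0.3, adjusted p = 0.56), and at 260 h 1.01% ± 0.1003 and 0.871% ± 0.488 (exact permutation p = 0.6, adjusted p = 0.8). The difference of knockout minus wild type at 260 h was 0.417 percentage points without wild-type library 1 and turned sign to −0.012 without wild-type library 2, and at 360 h it was 0.346 without knockout library 1. Between the times it was lower at 360 h in each genotype (exact permutation p = 0.1 each, the smallest 3 against 3 libraries can give, adjusted p = 0.243) and the wild-type difference was −0.395 percentage points without library 1 of 260 h and −0.824 without library 2 of 260 h. Cells of the pre-meiotic class, whose X-linked share at 260 h was 2.25% ± 0.0601 in knockout and 2.04% ± 0.401 in wild type (exact permutation p = 0.4, adjusted p = 0.589), were fewer at 360 h as well. They went from 27.1% to 1.86% of the cells in wild type and from 30.9% to 7.495% in knockout, with no overlap of the libraries (exact permutation p = 0.1 each, adjusted p = 0.243). In late pachytene cells at 360 h it was 0.298% ± 0.0907 in knockout (cluster 4) and 0.174% ± 0.0371 in wild type (cluster 5), with an exact permutation p = 0.2 (adjusted p = 0.415). None of these differences could pass 0.05 in this design.

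Cells of the authors' pre-meiotic class made up 30.9% ± 4.45 of the knockout and 27.1% ± 16.5 of the wild-type libraries at 260 h (SD, n = 3 each; exact permutation p = 0.8, adjusted p = 0.914). Wild-type library 1 had 24 of its 52 cells in that class and an X-linked share of 1.43%. The difference in that class was 13.2 percentage points without wild-type library 1 and turned sign to −1.75 without wild-type library 2. The early pachytene cells of wild-type libraries 1 and 2 stood in cluster 2 (25 and 56 cells, with 1 further cell of library 2 in cluster 3). Those of wild-type library 3 (72 cells) and of the knockout libraries of 260 h (141 cells) were all in cluster 3. At 360 h the class made up 7.495% ± 6.49 in knockout and 1.86% ± 0.693 in wild type (exact permutation p = 0.4, adjusted p = 0.589), and the late pachytene class 89.7% ± 9.17 and 98.1% ± 0.693 (exact permutation p = 0.4, adjusted p = 0.589). Knockout library 1 of 360 h had all 77 cells in the late pachytene class. Without it the differences were 9.39 and −13.6 percentage points, and without knockout library 2 they were 3.76 and −4.89. Gene UMIs per spike-in UMI at 360 h were 12.6 ± 0.439 in knockout and 22.5 ± 7.73 in wild type, with no overlap of the libraries (exact permutation p = 0.1, adjusted p = 0.243), and at 260 h 9.54 ± 0.991 and 12.1 ± 6.05 (exact permutation p = 0.8, adjusted p = 0.914). The difference of knockout minus wild type at 360 h was −9.83 and became −5.44 without wild-type library 3. At 260 h it was −2.59, became −4.97 without wild-type library 1 and turned to 0.817 without wild-type library 3. The median cell of a library had 104843 ± 4034 gene UMIs in knockout and 196455 ± 78290 in wild type at 360 h (exact permutation p = 0.1, adjusted p = 0.243), a difference of −91612 that became −46412 without wild-type library 3.

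**Figure D3:**
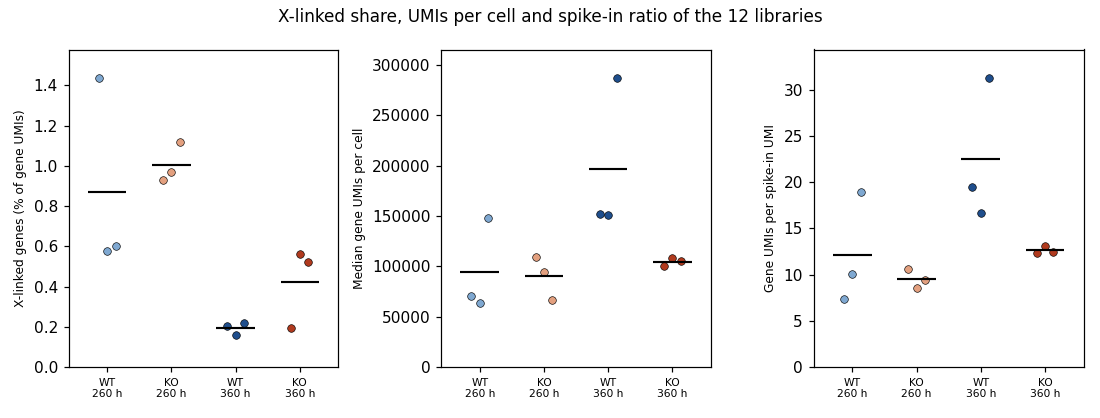
X-linked share of UMIs in percent, median gene UMIs per cell, and gene UMIs per spike-in UMI for each library in the 4 groups; points are libraries and bars means of 3. At 360 h the knockout libraries had 12.6 gene UMIs per spike-in UMI on average and the wild-type libraries 22.5.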

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

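The tests of cells of earlier classes, of the stage of late pachytene cells, of fewer UMIs per cell, of pre-meiotic cells at 260 h and of sequencing depth, and the simulated and split values of the hold, were chosen only after the results they bear on were seen.

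The knockout libraries differed from wild type in 4554 genes at 360 h. Cells of the pre-meiotic and early pachytene classes are argued against as the whole cause, since 4297 of the 4554 calls were found among late pachytene cells alone, and fewer UMIs per cell likewise, since 3808 were found with each cell thinned to 40000 UMIs. A hold of all these genes between the wild-type levels of 260 h and 360 h is argued against by 15.3% of the called genes (exact 95% interval 14.3% to 16.4%), which lay beyond wild type at 260 h in the same direction, where simulated holds with the same shared libraries gave 0.666% (0.362% to 0.890% in 20) and splits with no shared knockout library gave 3.55% to 23.6%, under 5% in 2 of 6. An earlier stage of the knockout cells within the late pachytene class cannot be told apart from the genotype, since all 220 of them at 360 h were in cluster 4, with no wild-type cell of 360 h and 2 of 260 h, and a stage between the collection times could lie beyond both, with animal or litter differences open as well because the labels do not give them. Of the 10 splits of the 6 libraries none other than the real one called a gene (highest other 0, real 4554), and 10 splits are too few for a share under 0.05.

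Of 265 genes lower in knockout at 260 h, 253 were called lower without pre-meiotic cells, which argues against more of those cells in knockout, although nearly all cells left were in cluster 2 in wild-type libraries 1 and 2 and in cluster 3 in library 3 and knockout. Free RNA in the wild-type libraries is argued against as the whole cause: it would give the same excess of CPM in every cell class, as 6 Leydig and macrophage genes did (0.759 to 1.50 in pre-meiotic over other cells), but over the 265 genes that ratio had a median of 0.297 and an upper quartile of 0.419. Free RNA stays open, and the axoneme, pachytene, metabolic and piRNA lists were lower within pre-meiotic cells too (median log2 fold changes −0.98, −1.07, −1.14 and −0.52). Whether wild-type libraries 1 and 2 were further along than library 3 cannot be told apart from the genotype: genes called lower without a wild-type library had a median against that single library of −1.44 for library 3 (346 genes, −2.30 against the others), −0.87 for library 1 (459 genes, −1.66) and −2.83 for library 2 (93 genes, −2.28), medians over 3 different gene sets that do not rank the libraries, while on the first principal component library 3 (−94.7) lay nearer the knockout libraries (−131 to −115) than library 1 (−65.2) or 2 (−56.7). The 10 splits are too few for a share under 0.05 here too (real 383, highest other 0).

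Gene UMIs per spike-in UMI at 360 h were lower in knockout, and the spike-in share was higher, at 7.34% ± 0.232 against 4.55% ± 1.31, with the difference of the first from −9.83 to −5.44 without wild-type library 3. Sequencing depth per cell would lower spike-in UMIs as well, but spike-in UMIs per cell had a ratio of 1.04 of knockout to wild type. The amount of spike-in added, the capture of RNA and the RNA content of the cells stay open, and none was tested.

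For the changes with time the 10 splits are too few for a share under 0.05: the highest other split called 0 genes in wild type (real 8082) and 0 in knockout (real 4759). For the difference between times, 7 of 100 splits, the real one included, called at least 1030 genes (highest other 3685), a share that does not exclude chance. The 6 others all keep the genotype groups of 360 h and so hold the genotype effect of that time, and of the 92 splits that do not keep them the highest called 1 gene. The split with 3685 calls swaps the genotypes at 360 h. Its contrast is therefore the sum of the genotype effects of both times and not their difference.

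Genes whose knockout effect differed between 260 h and 360 h by the test of that difference are given as 360 h minus 260 h on the log2 scale. More positive at 360 h were Hsd3b1 (8.19) and C1qa (7.45), which stood at 22.5 and 12.1 CPM in wild-type library 1 of 260 h, 10.3 and 16.0 in library 2 and 0.364 and 0.0728 in library 3, and Dhrs3 (6.75), Acot13 (4.79), Anp32e (4.63), Sbk1 (4.54), Arhgap21 (4.32), Zfp820 (4.30), Tmem160 (4.29), Dip2c (4.21), Apaf1 (3.77), Fads1 (3.74), Mcmdc2 (3.12), Bend6 (3.11), Btbd18 (3.04), Prok2 (2.85), Ehmt1 (2.79), Sgo1 (2.74), Prdm9 (2.70), Hfm1 (2.44), Fkbp6 (2.402), Zcwpw1 (2.39), Crisp2 (2.23), Dnmt3b (2.15), Msh5 (2.10), Uchl1 (2.10), Tex12 (2.02), Hormad2 (1.89), Mcm5 (1.88), Mcm3 (1.83), Rnf2 (1.81), Trp53inp1 (1.55) and Kdm5a (1.14). More negative were Brd3 (−1.14), Tdrd7 (−1.33), Tbpl1 (−1.59), Tdrd6 (−1.65), Rps2 (−1.87), Mroh2b (−1.93), Rnf168 (−2.39), Prps1l1 (−3.07), Dmrtb1 (−3.13), Macrod2 (−3.34), Dnah10 (−3.34), Ccna1 (−3.52), Aurkc (−4.67), Hk1 (−4.68), Susd5 (−5.00), Gtsf2 (−5.13), Hyal6 (−5.28), Csl (−5.74), Arc (−5.81), Pou5f2 (−6.16), Zbtb42 (−6.52), Ovol2 (−6.74) and Hoxa4 (−7.55). The fitted values of Tnp2 (−9.54) and Tssk3 (−11.0) rest on groups with almost no UMIs, depend on the prior count and are no bounds.

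The lists whose knockout effect differed between the times (camera adjusted p) were synaptonemal complex and crossover (6.81e-07), meiotic entry (6.46e-05), mitochondrial (0.00267), X-linked (0.00390), piRNA pathway (0.0120), Leydig (0.0199) and Sertoli (0.0199), all more positive at 360 h, and spermatid (0.00390), more negative. With an estimated correlation none of these calls was kept.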

How the results depend on the processing

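The fits scaled by spike-in UMIs, without pre-meiotic cells, with 1 library of a group, within thinned late pachytene cells, and with the libraries of 360 h split were chosen after seeing the data. No called gene that is named changed direction under any alternative, except C1qa with time in wild type, which was 1.57 with wild-type library 3 as the only library of 260 h. Where a count below moved, the cause was not tested, apart from fits with fewer libraries, cells or genes.

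Leaving out a library ended the calls of 1 to 16 of the 37 named genes at 260 h, 1 to 13 of 90 at 360 h, 0 to 2 of 52 with time in wild type, 0 to 6 of 47 with time in knockout and 2 to 10 of 35 for the difference between times, and scaling by spike-ins ended 11, 23, 7, 7 and 13. Within pre-meiotic cells all 32 named genes tested at 260 h lost their call. Wild-type library 3 alone ended 18 of 37 at 260 h, 7 of 52 with time in wild type (besides C1qa) and 10 of 35 for the difference, and knockout library 1 alone 42 of 90 at 360 h, 12 of 47 with time in knockout and 16 of 35 for the difference.

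At 260 h the 383 genes became 953 with DESeq2, 176 with limma-voom, 687 with no filter, 230 with all barcodes of at least 500 genes, 181 with only the 6 libraries, 246 scaled by spike-ins, 600 without pre-meiotic cells, 122 with wild-type library 3 alone, 4 within pre-meiotic cells, and 115 to 577 leaving out a library. At 360 h the 4554 became 2602 with a mean CPM of at least 20, where 7526 genes were tested, 996 with knockout library 1 alone and 2600 to 4892 leaving out a library. With time in wild type the 8082 became 4212 with that filter and 4989 with wild-type library 3 alone. With time in knockout the 4759 became 2567 scaled by spike-ins, 2636 with knockout library 1 alone and 2764 to 4992 leaving out a library. For the difference between times the 1030 became 2204 with DESeq2, 1581 with no filter, 408 scaled by spike-ins, 636 with wild-type library 3 alone, 191 with knockout library 1 alone and 482 to 1133 leaving out a library. The overlap of 1237 became 712 to 1306 leaving out a library, and that of 2060 became 1231 to 2215. Beside the change with time in knockout, the knockout effect at 360 h shared 195 and 733 genes in these directions. Beside that of 260 h it shared 2 and 4. With the wild-type libraries of 360 h split, the first overlap was 498, 580 and 622 with library 1, 2 or 3 for the change with time and 654, 557 and 345 with libraries 1 and 2, 1 and 3 or 2 and 3, and the second 1260, 1305, 1482, 1160, 1349 and 843.

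Every list call was lost in camera with an estimated correlation, and fry kept 1 of 7 at 260 h, 7 of 12 at 360 h, 13 of 14 with time in wild type, 8 of 10 in knockout and 1 of 8 for the difference. The X-linked list at 260 h turned direction without pre-meiotic cells (adjusted p = 0.614), where the X-linked and piRNA lists with time in knockout (0.220 and 0.660) and the Sertoli list for the difference (0.0830) were lost. There 5 lists not called before were called: meiotic entry (0.00458) and mitochondrial (0.0408) at 260 h, mitochondrial with time in wild type (0.0170), and DNA replication (0.0388) and spermatogonia (0.0191) for the difference. Leaving out a library gave adjusted p from 1.61e-12 to 0.838 for the ribosomal protein list at 260 h, with the direction turned at 0.838 without wild-type library 3. For the peritubular, endothelial, blood and immune list, which was not called, it gave 0.00128 to 0.824 at 260 h, 8.26e-04 to 0.985 with time in wild type and 0.0154 to 0.888 for the difference between times, each lowest without wild-type library 3 of 260 h, with the direction turned there at 260 h and for the difference. Of the lists not called, leaving out some library called 8 of 15 at 260 h, 1 of 10 at 360 h, 4 of 8 with time in wild type, 3 of 12 in knockout and 5 of 14 for the difference. Besides the peritubular list, and with the lowest adjusted p, these were at 260 h Leydig (3.1e-05), meiotic division (0.00600), synaptonemal complex (0.00600), meiotic entry (0.0113), Y-linked (0.0347), DNA replication (0.0457) and spermatogonia (0.0457), and at 360 h Leydig (0.0150). With time in wild type they were ribosomal protein (0.00232), DNA replication (0.0119) and mitochondrial (0.0129), and in knockout synaptonemal complex (0.00439), ribosomal protein (0.0296) and mitochondrial (0.0493). For the difference they were spermatogonia (4.05e-05), ribosomal protein (0.00283), axoneme (0.00399) and DNA replication (0.0155).

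The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated from −0.20 to 0.17, 1 of 18 over 0.1, and 2 of 12 libraries correlated best with their own number. With the replicate block the counts were 338, 4026, 7316, 4394 and 775, each within 1.5 times. In simulated counts most 2-fold changes at a typical level were not detectable with 3 libraries per group, at a depth that was not varied there. With each cell thinned to 40000 UMIs, where 15171 genes were tested, the counts were 338, 4245, 7356, 4874 and 1143, each within 1.5 times of the count at full depth.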

Other observations

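The list of genes beyond both wild-type groups without pre-meiotic cells, the simulated and split values of the wild-type change, the 7 cells of cluster 2, and the test around Zfp541 were chosen after their values were seen, as were the genes here that the rule for named genes did not pick.

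Part of the knockout difference at 360 h lay outside the range of the wild-type groups, a part whose size depended on the libraries used. Of the 1811 genes higher in knockout at 360 h, 374 were also called higher than in wild type at 260 h (20.7%, exact 95% interval 18.8% to 22.6%), and of the 2743 lower, 323 were also called lower (11.8%, 10.6% to 13.0%). Higher than both were Six5 (log2 fold change 4.95 against wild type at 260 h and 5.68 at 360 h), Bend6 (5.19 and 6.22), Pbx3 (4.16 and 3.601), Iqgap2 (4.99 and 4.58), Fam81a (4.90 and 4.71) and Dtx4 (4.78 and 4.10), and, of the meiotic lists, Prdm9 (3.52 and 3.92), Zcwpw1 (1.89 and 3.72), Hfm1 (1.13 and 2.45) and Mcmdc2 (1.07 and 3.17). Lower than both were Susd5 (−5.59 against 260 h), Hoxa4 (−4.54), Tnfaip2 (−4.51 and −6.40), Slc8a2 (−4.52 and −3.86), Hk1 (−2.33) and Tdrd7 (−0.86). Without pre-meiotic cells the shares were 503 of 1940 (25.9%) and 410 of 2616 (15.7%), and 638 genes were beyond in both fits. Of the 4554 calls, 3297 (72.4%) went against the change called with time in wild type, a set that overlaps the genes beyond both groups. Over the 8082 genes called with time in wild type, knockout at 360 h stood at a median 44.8% of the wild-type change from wild type at 260 h. Simulated counts with no knockout effect at 360 h gave 95.7% (95.3% to 96.2% in 20), below 100% because the genes are chosen on the same wild-type libraries. With some wild-type libraries of 360 h choosing the genes and the others giving the change, the value was 40.6% to 50.1% over 6 splits.

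Of the knockout cells at 360 h, 7 were in the authors' cluster 2, 5 from library 2 and 2 from library 3. Their X-linked share averaged 2.49% (2.14% to 3.23%), against 0.453% in the 81 wild-type cells of that cluster at 260 h. Summed over those 7 cells Prdm9 was at 496 CPM, Stra8 at 731, Dmc1 at 540.5 and Zcwpw1 at 1135, against 3.9, 29.1, 61.3 and 103 in the wild-type cells of cluster 2. No test was made on cells.

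Among genes called at 260 h, Six5 (chromosome 7, 19094594 to 19098549, plus strand) and Gm4969 (Meiosin, 19099046 to 19118368, minus strand) are neighbours with facing 3′ ends. Gm4969 is therefore uncertain. Tmem160 lies 0.391 Mb from Zfp541. A change tied to that region was a hypothesis: of 139 tested genes that start within 5 Mb of Zfp541, 5 were called at 260 h (3.597% against 1.88% elsewhere), an odds ratio of 1.95 (exact 95% interval 0.620 to 4.71, Fisher's exact p = 0.194). The 5 calls are too few to tell, and the interval holds 1. At 360 h 30 of them were called, an odds ratio of 0.94995 (0.611 to 1.44, Fisher's exact p = 0.919). Of these 5 were higher and 25 lower, against 1811 and 2743 over all genes, and the odds ratio leaves direction out. The called genes nearest Zfp541, starting −0.126 to 0.113 Mb from it, were lower. They were Nop53 (log2 fold change −2.39), Napa (−2.23), Kptn (−1.28), Slc8a2 (−3.86) and Meis3 (−3.76). Tmem160, the next, was higher (6.53). A tie of direction to the region was not tested.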
